A study of Mus musculus with 2 samples.

How the data were processed

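Non-muscle cells of mouse hearts were measured in 2 samples, 1 library of db/+ mice and 1 library of db/db mice given 1% salt, and the genotype and treatment labels set the groups. Per the labels' protocols, hearts were flushed, minced and digested with collagenase I, cells were passed over strainers of 40, 30 and 20 µm, debris and red cells were removed, CD45-positive cells were depleted with magnetic beads, and libraries were made with the 10x Genomics 3' v3.1 kit with a target of 10000 cells each. Per the design text of the series, 4 male hearts per genotype were used; whether they were pooled before loading is not given in the sources used here, and cells cannot be assigned to single animals.

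The deposited values are raw UMI counts per gene and barcode, not normalized. Per the file headers, the matrices were written by Cell Ranger 6.0.2. The db/+ matrix held no barcode under 502 UMIs and the db/db and salt matrix none under 500, and how barcodes were chosen is not given in the sources used here. Per the submitters' processing notes, Cell Ranger and Seurat were used with the GRCm38 (mm10) genome; what Seurat was used for, and the annotation release, are not given in the sources used here. Of 31053 gene identifiers, 30934 were found in the GENCODE M21 annotation of GRCm38, which gave the coordinates, and 119 were not. Genes whose symbol occurs more than once (71 entries) were left out of the gene lists, Aldoa and Atp5o among them.

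Barcodes with at most 10% of UMIs from 13 mitochondrial genes and at least 500 detected genes were kept. In the db/+ library 609 of 5676 barcodes (10.7%) and in the db/db and salt library 544 of 4751 (11.5%) were above the mitochondrial limit, and 289 and 165 were below 500 genes. Doublets were called per library with Scrublet, at an expected rate of 0.8% per 1000 cells, which marked 83 of 5058 (1.64%) and 44 of 4201 (1.05%) cells, and these were removed. Barcodes that carried markers of more than 1 type stayed where Scrublet did not mark them. Clusters 11, 16, 17 (cardiomyocyte-like) and 23 (leukocyte-like) held such barcodes. Both libraries were clustered together without integration, on 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1, with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and scikit-learn 1.9.0.

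Clusters were named from marker lists fixed before the data were examined, by the mean share of cells with each marker: at least 60% for endothelial, fibroblast, pericyte, endocardial and lymphatic endothelial names, 50% for smooth muscle, proliferating, Schwann, mesothelial, adipocyte, erythroid and platelet names, 30% for cardiomyocytes and 20% for leukocytes. These thresholds were set after the data were seen. Names were tried in a fixed order. A cluster that reached no threshold, or that was shallow without a marker of its name among its leading genes, stayed unnamed. Endothelial subtypes came from a further clustering of endothelial-like cells without 182 genes that differ between the libraries or belong to the interferon and antigen lists, which gave 16 clusters, and a subtype name needed 3 of its markers among the top 30 genes and no other subtype with more markers among the top 10. This step was also chosen after the data were seen, and the 182 genes could still count as markers for a name.

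UMIs were summed per library and class and given as CPM of that class, which amounts to 21360490 and 18437568 UMIs in endothelial-like, 12190522 and 13583723 in fibroblast-like and 1614689 and 1808126 in smooth muscle-like cells, so that single genes are less precise in smooth muscle-like cells. The value of a gene is log2 of the db/db and salt CPM plus 10 over the db/+ CPM plus 10, which understates the ratio of low genes. Intervals are exact Poisson for counts and Clopper-Pearson for shares, at 95%, and intervals of list medians came from 1000 Poisson resamples; all of them cover counting error only. With 1 library per group no test was possible for shares, genes or lists. A list's value is the median over members with a mean of at least 10 CPM, where at least 5 members had it, and its percentile among 10000 random lists was taken from the 100 genes nearest in expression to each member. In all, 36 lists gave 122 medians. The lists were fixed before the data were examined, and which of them the text leads with was settled partly after their values were seen.

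The named genes followed a rule fixed before the data were examined. In classes with at least 100 cells per library, the 10 highest and 10 lowest log2 ratios were taken (5 and 5 in smooth muscle-like cells) among genes with at least 50 CPM and 30 UMIs in the higher library, a UMI in 5% of its cells, and at least 10% of the highest level in any other class of at least 50 cells, without mitochondrial, ribosomal protein, haemoglobin, Gm-numbered and Rik genes. Up to 4 members per list and class with the largest absolute ratio were added, with 10 of the genes at least 1.5-fold apart the same way in all 3 main classes (those with the largest smallest fold), Lepr and the sex check genes. Some genes that this rule takes are not reported here, and are left out of the plots, while list medians and counts include all measured members. Other members named beside a list's count were chosen after their values were seen. Cells were thinned to 1500 UMIs where shares of cells with a UMI or of cycling cells were compared.

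The procedure was tested on simulated counts drawn from the real means. Both libraries were drawn as Poisson counts from the same means, apart from the changed genes. The rates below thus cover counting error only, and not differences between hearts, preparations or mixed barcodes, which real libraries also carry. With 200 genes changed by known folds among 8182 in endothelial-like cells, all 68 changed 1.5-fold, all 66 changed 2-fold and all 66 changed 4-fold had the right sign, and 0 of 7982 unchanged genes passed 1.5-fold. Among 8824 genes in smooth muscle-like cells all changed genes had the right sign, and 43 of 8624 unchanged ones (0.499%) passed 1.5-fold. Of 200 simulated lists shifted 1.5-fold, 200 lay above the upper limit of random lists in each class, and of 200 unshifted ones 5 lay above the upper and 8 below the lower limit in endothelial-like cells, and 5 above and 10 below in smooth muscle-like cells.

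Alternatives fixed before the data were examined were mitochondrial limits of 5 and 20%, minimums of 200 and 1000 genes, doublets kept, resolutions of 0.5 and 2, 4000 variable genes, each library clustered alone, the 2% of cells with the most UMIs left out, other denominators of shares, TMM factors (edgeR 4.0.16 in R 4.3.3, used for scaling only), the median of gene ratios, the mean of each cell's CPM, pseudocounts of 1 and 50 CPM, cells thinned to 1500 UMIs, 5% free RNA removed, and list floors of none and 50 CPM. TMM factors differed between the libraries by 0.081, 0.031 and 0.030 on the log2 scale, before the pseudocount, in endothelial-like, fibroblast-like and smooth muscle-like cells. Added after the data were seen were the pericyte-like share without mixed barcodes, pericyte-like and smooth muscle-like cells as 1 class, subtypes named without regard to the top 10 genes, and endothelial lists without clusters of over 95% of 1 library. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and blastn 2.17.0.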

Results

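Single-cell RNA sequencing was applied to non-muscle cells of mouse hearts. db/+ mice carry 1 mutated copy of the leptin receptor gene Lepr and served as the controls. db/db mice carry the mutation on both copies, which is known to cause obesity and diabetes, and were given 1% salt; the series title names this group as a model of heart failure with preserved ejection fraction. The samples were described as depleted of cardiomyocytes and of CD45-positive leukocytes, with 4 male hearts per genotype, and each group was measured as 1 library. The db/+ library held 5676 barcodes and 44935235 UMIs (molecules counted once each), and the db/db and salt library held 4751 barcodes and 40974634 UMIs, where about 10000 cells per library had been targeted. After filtering, 4865 and 4100 cells remained, with a median of 7037 and 7787.5 UMIs and of 2690 and 2891 detected genes per cell.

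There were no replicates, so no test was run and no p-value is given. Levels are UMI sums per class and library, scaled to the UMI total of that class as CPM, with exact Poisson 95% intervals. Shares have exact binomial (Clopper-Pearson) 95% intervals, and both cover counting error only. Ratios are log2 of the db/db and salt CPM plus 10 over the db/+ CPM plus 10. Genotype and salt differed together and cannot be separated.

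Lepr, the gene mutated in db mice (ENSMUSG00000057722), had most of its UMIs in fibroblast-like cells, with 345 UMIs or 28.3 CPM (95% interval 25.4 to 31.5) in db/+ and 338 UMIs or 24.9 CPM (22.3 to 27.7) in db/db and salt. Endothelial-like cells held 8 and 4 Lepr UMIs and smooth muscle-like cells 4 and 5. The 28 and 30 lymphatic endothelial-like cells held 18 and 4, or 38.0 and 10.3 CPM, with overlapping intervals. Counts of transcript 3' ends do not read the db mutation, so these values do not check the genotype labels. Both libraries carried Y-linked transcripts, with Ddx3y at 105 and 103 CPM in endothelial-like cells, and nearly no Xist, the RNA of the inactive X chromosome (0 and 2 UMIs there).

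The make-up of the suspension was compared first. Endothelial-like cells, marked by Pecam1, Cdh5 and Cldn5, were 62.7% of the kept cells in db/+ (61.3 to 64.1%, 3050 cells) and 62.6% in db/db and salt (61.1 to 64.1%, 2567 cells). Fibroblast-like cells, marked by Pdgfra, Dcn and Col1a1, were 24.7% (23.5 to 26.0%, 1203 cells) and 26.5% (25.2 to 27.9%, 1088 cells). Smooth muscle-like cells, with Myh11, Acta2 and Tagln as leading genes, were 2.38% (1.97 to 2.85%, 116 cells) and 2.93% (2.43 to 3.49%, 120 cells). Pericyte-like cells, led by Kcnj8, Abcc9 and Vtn, were 2.80% (2.35 to 3.30%, 136 cells) and 2.07% (1.66 to 2.56%, 85 cells). For each of these classes the intervals of the libraries overlapped. Proliferating-like cells, led by Mki67, Cenpf and Top2a, were 2.92% (2.46 to 3.43%, 142 cells) in db/+ and 1.10% (0.802 to 1.47%, 45 cells) in db/db and salt.

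The remaining cells were endocardial-like (58 and 73 cells, 1.19 and 1.78%), cardiomyocyte-like (64 and 46, 1.32 and 1.12%), lymphatic endothelial-like (28 and 30, 0.576 and 0.732%), Schwann-like (19 and 8, 0.391 and 0.195%), leukocyte-like (12 and 11, 0.247 and 0.268%) or stayed without a name (37 and 27, 0.761 and 0.659%). Barcodes of the cardiomyocyte-like and leukocyte-like clusters also carried endothelial transcripts, with each endothelial marker found in 90.7 and 82.2% of them on average. The thresholds that kept proliferating-like, cardiomyocyte-like, endocardial-like, lymphatic, leukocyte-like and unnamed cells out of the endothelial class were set after the data were seen. Collagenase digestion, strainers of 40, 30 and 20 µm, red cell lysis and the CD45 beads can act on all of these shares, and their effect was not tested. The log2 ratio of the pericyte-like share, -0.43, became 0.12 when cluster 16 was left out, whose barcodes also carried endothelial transcripts (each endothelial marker was found in 96.5% of them on average), and that of the smooth muscle-like share, 0.30, became -0.11 with up to 20% mitochondrial UMIs allowed.

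**Figure D1:**
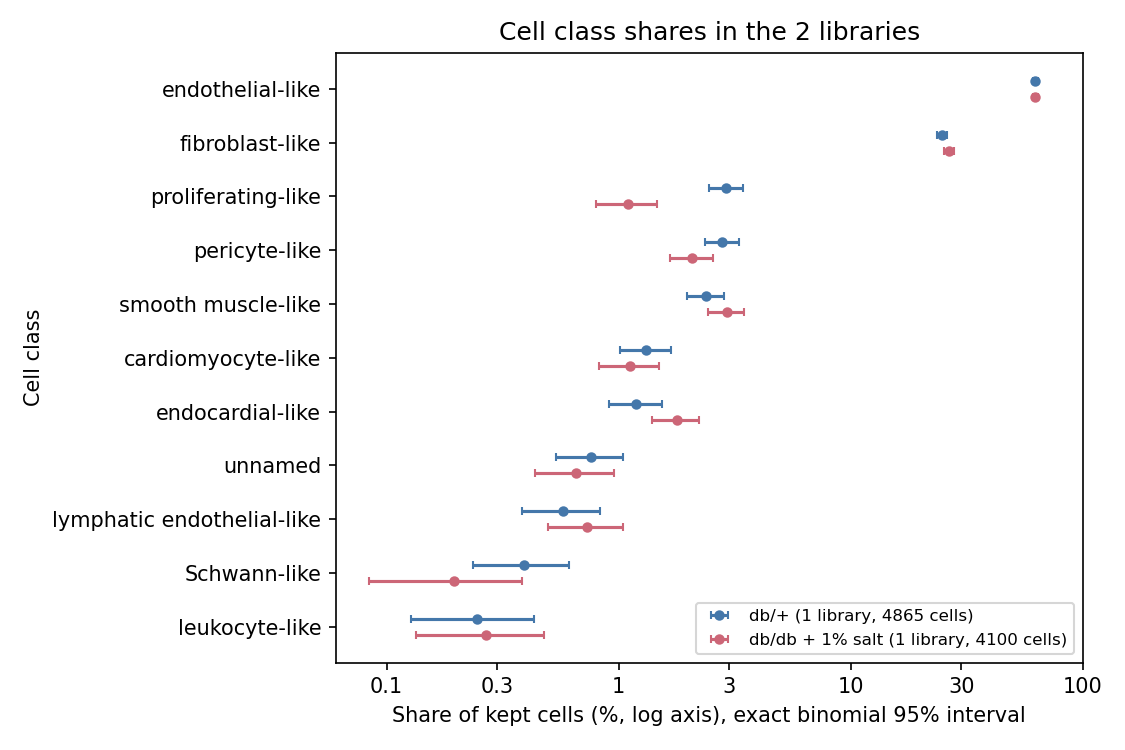
Share of kept cells in percent (x axis, log scale) for each class (y axis) in the db/+ library (blue) and the db/db and salt library (red), as points with exact binomial 95% intervals that cover counting error only. Endothelial-like cells were 62.7 and 62.6% of the cells, and proliferating-like cells 2.92 and 1.10%.

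Cells in the cycle were also counted per cell, as those with UMIs of at least 3 of 8 proliferation markers, among them Mki67, Top2a and Birc5. With every cell thinned to 1500 UMIs they were 1.89% in db/+ (1.52 to 2.33%, 87 of 4604) and 0.882% in db/db and salt (0.615 to 1.22%, 35 of 3970). Among cells with more endothelial than fibroblast marker UMIs the shares were 2.47% (82 of 3323) and 1.14% (32 of 2807), and among cells with more fibroblast marker UMIs 0.395% (5 of 1267) and 0.261% (3 of 1150), which gives the level in a type with few such cells. Thinning left out 261 and 130 shallower cells, and without it the shares over all cells were 3.19 and 1.05%. Whether free RNA added to these calls was left open.

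In endothelial-like cells, transcripts of antigen presentation and of the interferon response were lower in db/db and salt than in db/+. Cd74, the invariant chain of class II MHC (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652, GRCm38), was at 214 CPM (208 to 221) in db/+ and 2.28 CPM (1.64 to 3.08) in db/db and salt, a log2 ratio of -4.19. Lower as well were the class II chains H2-Ab1 (87.6 and 2.71 CPM, log2 ratio -2.94) and H2-Aa (72.3 and 2.55 CPM, -2.71). So were the peptide transporter Tap1 (154 and 33.8 CPM, -1.90), the class I genes H2-Q7 (366 and 41.6 CPM, -2.87) and H2-Q6 (161 and 28.0 CPM, -2.17), the interferon-inducible GTPases Iigp1 (663 and 138 CPM, -2.18) and Igtp (165 and 27.1 CPM, -2.24) and the chemokine Cxcl9 (278 and 59.6 CPM, -2.05). Cyp26b1, a cytochrome P450 that degrades retinoic acid (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908), was higher in db/db and salt, at 381 CPM (372 to 390.1) against 44.1 CPM (41.3 to 47.0), a log2 ratio of 2.86. H2-Q6 and H2-Q7 have near-identical relatives, between which UMIs can be split, so their single values are uncertain.

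Of the 15 measured members of the antigen presentation list, 14 were at least 1.5-fold lower in these cells and none higher, with a median log2 ratio of -1.43 (95% counting interval -1.49 to -1.40) that lay below all 10000 random lists matched on expression. H2-K1, a class I heavy chain, was at 2207 and 778 CPM (-1.49), and B2m, its light chain, at 3403 and 1359 CPM (-1.32). Of the 20 interferon response genes, 18 were at least 1.5-fold lower and none higher, with a median of -1.09 (-1.15 to -1.03), again below all random lists. Bst2, a viral tethering factor (968 and 255 CPM, -1.88), and the GTPases Gbp3 (236 and 58.0 CPM, -1.85) and Gbp4 (-1.80) were among them. The list of leukocyte adhesion and inflammation had a median of -0.35 (-0.40 to -0.32), and of -0.23 with a pseudocount of 50 CPM. Of 14 members 5 were lower, Cxcl9, Cxcl10 (-1.87), the adhesion molecules Vcam1 (-1.42) and Icam1 (-0.75), and Ccl2 (-0.67).

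Some clusters of endothelial-like cells came almost wholly from 1 library, while most held cells of both. Cluster 4 (760 cells of db/+ and 9 of db/db and salt, led by Iigp1, Gbp4 and Igtp), cluster 13 (146 and 0, led by Cd74, H2-Eb1 and H2-Ab1) and cluster 19 (68 and 1, led by Cd74, H2-Ab1 and H2-Aa) were the cells of db/+ nearly alone, and the other 2076 of its 3050 endothelial-like cells lay in shared clusters, such as 2 (407 and 491), 5 (350 and 308), 6 (371 and 245) and 10 (103 and 147). Clusters 1 (368 and 659) and 3 (268 and 599, led by Cyp26b1 and Aqp1) held more cells of db/db and salt. Cluster 9 was led by the interferon-inducible genes Ifit1, Isg15 and Oasl1 (199 and 100 cells). Leaving out clusters 4, 13 and 19, a choice made after the data were seen, gave a median of -0.72 for antigen presentation and -0.77 for the interferon response. Haemoglobin and other erythroid transcripts, taken as a sign of red cell RNA, were lower by a median log2 ratio of -0.56 over 5 genes and summed to 4049 and 2713 CPM over the erythroid markers, and fibroblast markers summed to 101 and 197 CPM.

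**Figure D2:**
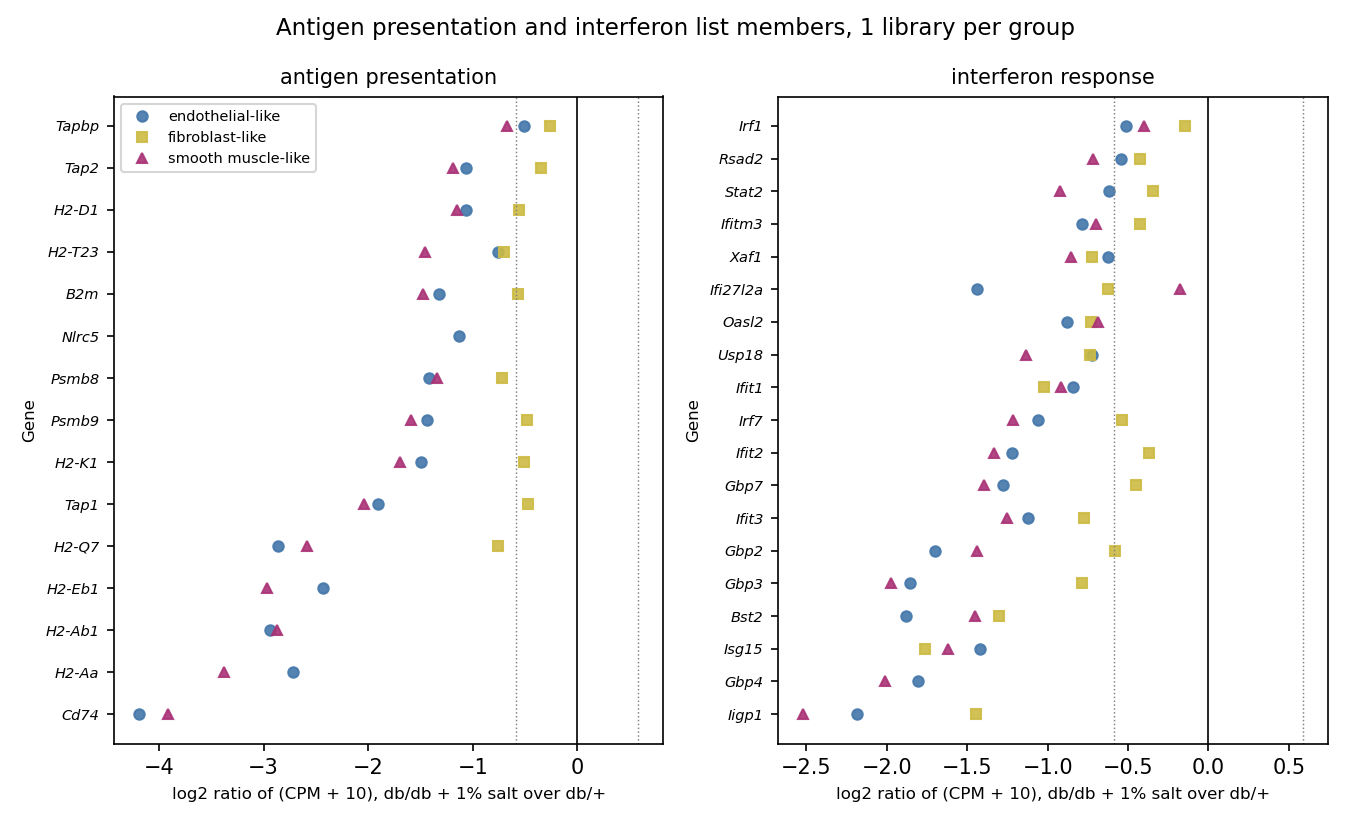
Log2 ratio of CPM plus 10, db/db and salt over db/+ (x axis), for measured members (y axis) of the antigen presentation list (left) and the interferon response list (right) in endothelial-like (circles), fibroblast-like (squares) and smooth muscle-like cells (triangles), with dotted lines at 1.5-fold. In endothelial-like cells the list medians were -1.43 and -1.09, and Cd74 was at -4.19.

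Per cell, with every cell thinned to 1500 UMIs, a Cd74 UMI was found in 7.14% of db/+ endothelial-like cells (6.22 to 8.15%) and 0.285% of those of db/db and salt (0.115 to 0.587%). In fibroblast-like cells, which should lack Cd74, the shares were 0.25 and 0.184%, so that the db/db and salt share lay at the level of background. Cyp26b1 UMIs were found in 4.63% (3.89 to 5.47%) and 28.8% (27.0 to 30.6%) of endothelial-like cells, against 0.0833 and 0.368% of fibroblast-like cells. Thinning left out 222 and 112 endothelial-like cells. Unthinned, at median depths of 5122.5 and 5355 UMIs, the shares were 10.8 and 0.506% for Cd74 and 11.9 and 45.7% for Cyp26b1, and in fibroblast-like cells, at 9764 and 12036 UMIs, 1.25 and 0.276% for Cd74 and 0.998 and 3.68% for Cyp26b1.

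Other endothelial genes with higher levels in db/db and salt were Ocel1 (27.5 and 98.5 CPM, log2 ratio 1.53), the proteoglycan Spock2 (13.3 and 54.9 CPM, 1.48), Ccdc85b (67.4 and 147 CPM, 1.02), the ubiquitin ligase Trim37 (0.95), Igfbp3, which binds insulin-like growth factors (132 and 260.0 CPM, 0.93), the matrix protein Fbln2 (215 and 402 CPM, 0.87), the immediate early receptor Nr4a1 (0.81), Lrrc3b (0.80) and the monooxygenase Fmo2 (144 and 257 CPM, 0.79). Fbln2 and Fmo2 had their highest level in fibroblast-like cells. Dbp, a transcription factor driven by the circadian clock, was at 69.3 and 7.0 CPM (-2.22).

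The other lists had medians between -0.21 and 0.14 in endothelial-like cells, where the median over all 8182 measured genes was 0.057. Glycolysis and glucose uptake had a median of -0.10, with Hk1 at 0.66 and Pfkfb3 at -0.89. Medians were 0.065 for fatty acid uptake, -0.019 for fatty acid oxidation, -0.014 for the respiratory chain, 0.13 for cholesterol synthesis, 0.059 for vascular tone and nitric oxide, with the endothelin receptor Ednrb at 0.60, and -0.038 for oxidative stress. They were 0.13 for VEGF, Notch and angiopoietin signalling, 0.10 for TGF-beta and BMP signalling, with Bmp6 at 0.76, 0.13 for junctions and barrier, -0.0071 for coagulation, 0.092 for insulin, IGF and leptin signalling, with Igfbp5 at 0.86, -0.068 for hypoxia and 0.029 for the unfolded protein response. Matrix lists were at 0.057 for fibrillar collagen, 0.015 for basement membrane, with Col15a1 at -0.93, 0.14 for matrix degradation and 0.051 for fibroblast activation. The others were glucocorticoid response (-0.11), mineralocorticoid and salt handling (0.10), senescence (0.046), proliferation (-0.21), contractile (0.045) and early response and dissociation (0.069). The share of random lists with a lower median, which describes these libraries only, was 0.08% for proliferation, 0.3% for glycolysis, 0.42% for hypoxia, 0.75% for the glucocorticoid response and 2.11% for oxidative stress, 97.0% for VEGF, Notch and angiopoietin signalling and 97.9% for junctions, and between 6.44 and 93.2% for the others of this group. With TMM scaling, the medians of fatty acid uptake (-0.017), fibrillar collagen (-0.0055), senescence (-0.033) and early response (-0.011) were below 0. With cells thinned, that of proliferation was 0.072, and over members of at least 50 CPM that of TGF-beta was -0.066.

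Endothelial subtypes were named from clusters made without 182 genes that were at least 1.5-fold apart or in the interferon and antigen lists, a step chosen after the data were seen. Angiogenic endothelial-like cells, led by Apln, Pgf and Adm, were 11.9% of endothelial-like cells in db/+ (10.7 to 13.1%) and 7.83% in db/db and salt (6.82 to 8.94%). Capillary endothelial-like cells, with Car4, Timp4 and Rgcc, were 18.2% (16.8 to 19.6%) and 15.1% (13.7 to 16.5%). Arterial endothelial-like cells, with Gja4 and Fbln5, were 10.4% (9.30 to 11.5%) and 12.0% (10.8 to 13.4%). Venous endothelial-like cells were 6.75% (5.89 to 7.70%) and 5.61% (4.75 to 6.57%), and 52.9 and 59.4% stayed without a subtype. The venous cells came from a cluster of 185 and 130 cells, with Nr2f2 and Vcam1 as leading genes, and 1 of 21 and 14 cells led by Vwf. The larger cluster had just the 3 venous markers needed. Vcam1, 1 of them, was among the genes left out of the clustering for differing between the libraries, so the venous name and shares rest partly on it. A cluster of 175 and 213 cells with 3 capillary markers stayed unnamed because Angpt2, an angiogenic marker, was among its top 10 genes and no capillary marker was. With it counted, capillary cells were 23.9% (22.4 to 25.5%) and 23.4% (21.7 to 25.1%), so the lower capillary share in db/db and salt rests on that choice. The antigen presentation median was -1.19 in angiogenic, -1.28 in arterial, -1.25 in capillary and -1.73 in venous cells, and the interferon median -0.85, -0.87, -0.98 and -1.14. Cyp26b1 was higher in each, by a log2 ratio of 2.51 in angiogenic, 2.96 in arterial, 3.52 in capillary and 1.61 in venous cells. Cd74 and H2-Eb1 were among the leading genes of a venous cluster, and Cd74 was at a log2 ratio of -7.11 in venous and -0.96 in angiogenic cells.

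In fibroblast-like cells, genes of fibroblast activation were lower and genes of cholesterol synthesis were higher in db/db and salt. Lpl, the lipase that frees fatty acids from lipoproteins (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448), was at 733 CPM (718 to 748) in db/+ and 1508 CPM (1488 to 1529) in db/db and salt, a log2 ratio of 1.03.

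Of 17 measured members of the fibroblast activation list, 10 were at least 1.5-fold lower and none higher, with a median log2 ratio of -0.73 (-0.76 to -0.64), below all random lists. Among them were the matrix proteins Cilp (276 and 130.1 CPM, -1.03), Comp (93.7 and 41.1 CPM, -1.02) and Postn (683 and 407 CPM, -0.73), the protease inhibitor Timp1 (179 and 96.9 CPM, -0.82) and Acta2, a smooth muscle actin (-0.69), while smooth muscle markers, Acta2 among them, summed to 409 and 274 CPM in the same cells. Of 15 cholesterol synthesis and lipogenesis genes, 9 were at least 1.5-fold higher and none lower, with a median of 0.69 (0.58 to 0.75), above all random lists. They included Idi1 (14.4 and 41.6 CPM, 1.08) and Fdps (21.8 and 51.3 CPM, 0.95), enzymes of the isoprenoid branch, Insig1, a sterol-regulated brake of the pathway (35.2 and 77.3 CPM, 0.95), Hmgcs1 (0.73) and the fatty acid synthase Fasn (0.63). With a pseudocount of 50 CPM these medians were -0.44 and 0.26.

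The interferon response was lower in fibroblast-like cells too, with 10 of 19 members at least 1.5-fold lower and a median of -0.62 (-0.69 to -0.58). Isg15 was at 72.4 and 14.3 CPM (-1.76), Iigp1 at 71.4 and 19.9 CPM (-1.45) and Bst2 at 224 and 84.7 CPM (-1.30). Antigen presentation had a median of -0.53 (-0.58 to -0.51), with 3 of 10 lower, H2-Q7 (-0.75), the immunoproteasome subunit Psmb8 (-0.72) and H2-T23 (-0.71). In the leukocyte adhesion and inflammation list 5 of 11 were lower (median -0.41), among them the monocyte chemokines Ccl7 (135 and 38.5 CPM, -1.58) and Ccl2 (-0.84). Complement had a median of -0.29 with 3 of 9 lower, C7 (-1.04), C4b (-0.99) and C3 (1050 and 577 CPM, -0.85). The unfolded protein response had a median of 0.32 with Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, at 26.7 and 51.8 CPM (0.75).

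Fibrillar collagen had a median of -0.13 over 24 genes, with Eln, the elastin gene, 1.5-fold or more higher (417 and 656 CPM, 0.64); with cells thinned to 1500 UMIs the median was -0.025. The glucocorticoid list was at -0.18, with Zbtb16 at -1.01 and the metallothioneins Mt2 and Mt1 at -0.68 and -0.65, the contractile list at -0.21, matrix degradation at -0.11, with the protease Mmp3 at 93.6 and 33.6 CPM (-1.25), and pericyte identity at -0.11. Pericyte markers summed to 296 and 231 CPM in these cells. The glucocorticoid and contractile medians lay below all random lists, and fewer than 1% of random lists lay below those of fibrillar collagen (0.1%), pericyte identity (0.25%), oxidative stress (0.41%) and matrix degradation (0.51%). At the other end, the unfolded protein response lay above all random lists. Mineralocorticoid and salt handling lay above 99.9% of them and basement membrane above 97.0%. Fatty acid uptake was at -0.20, also below all random lists, although Lpl was higher, and turned to between 0.11 and 0.20 under 4 other settings of clustering or cell filters. Pericyte identity turned to 0.0070 with at least 1000 genes per cell. The others were mineralocorticoid and salt handling (0.14, and -0.0036 with cells thinned), basement membrane (0.088), vascular tone (0.071), fatty acid oxidation (0.066), glycolysis (0.042), the respiratory chain (0.046), hypoxia (0.046), senescence (0.046) and early response (0.013). Below 0 were insulin, IGF and leptin signalling (-0.012), TGF-beta and BMP signalling (-0.015, with Tgfbi at -0.83), junctions (-0.018), VEGF and Notch (-0.022), coagulation (-0.025), mesenchymal transition (-0.043), the renin-angiotensin system (-0.069, and 0.024 with cells thinned) and oxidative stress (-0.093).

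Other fibroblast genes with higher levels were the glutathione transferases Gstp1 (20.8 and 63.8 CPM, 1.26) and Gsta3 (200 and 452 CPM, 1.14), which have close relatives between which UMIs can be split, the matrix protein Spon2 (102 and 232 CPM, 1.11) and the clock factor Arntl (26.2 and 66.7 CPM, 1.08). Lower were the clock genes Dbp (118 and 20.2 CPM, -2.08), Nr1d1 (142 and 36.9 CPM, -1.69) and Nr1d2 (-1.18) and the interferon-inducible Mndal (-1.09). In each of the 4 fibroblast clusters the activation median was below 0 (cluster 0 -0.53, cluster 7 -0.66, cluster 8 -0.51, cluster 14 -0.36) and the cholesterol median above 0 (0.78, 0.37, 0.56 and 0.19). Cluster 7 had Cilp, Timp1 and Postn among its leading genes and held 280 and 205 cells. Each activation median by cluster was smaller in size than the -0.73 over all fibroblast-like cells, and how far cell numbers per cluster add to that value was not tested.

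**Figure D3:**
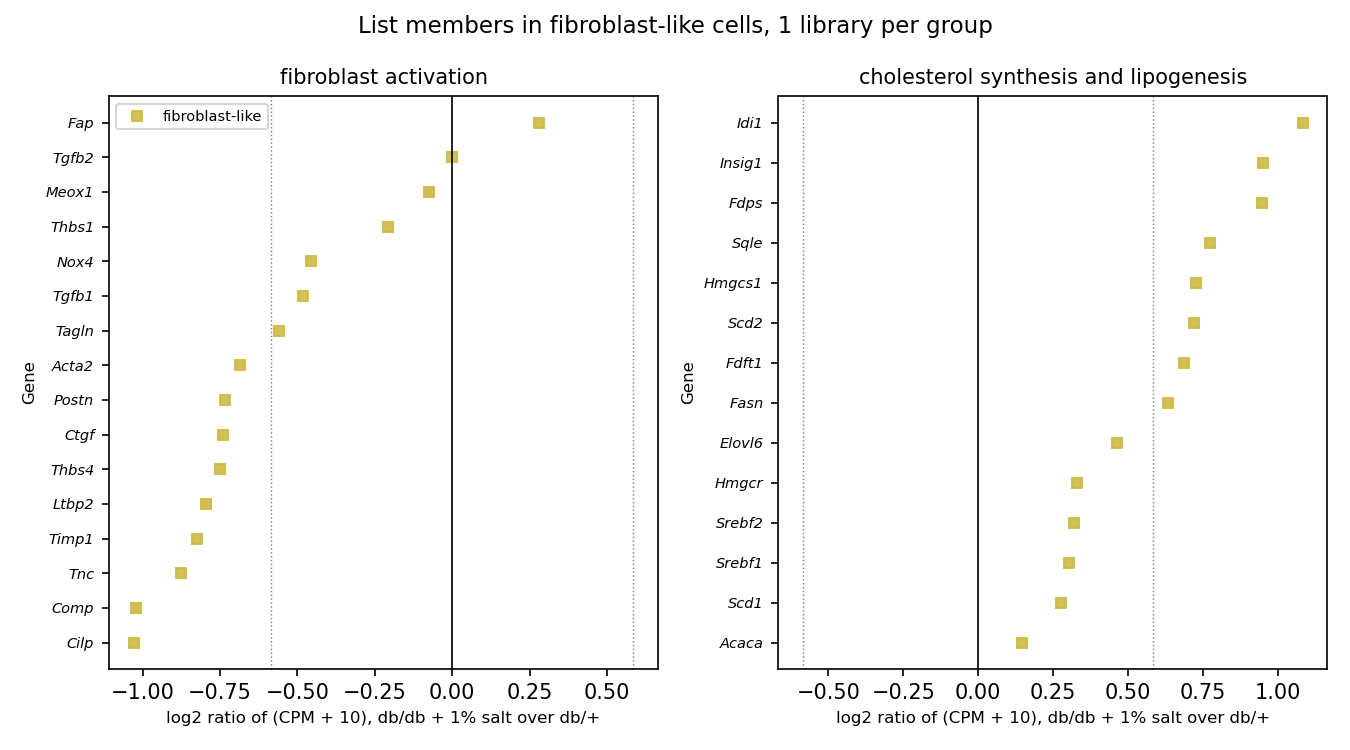
Log2 ratio of CPM plus 10, db/db and salt over db/+ (x axis), in fibroblast-like cells for measured members (y axis) of the fibroblast activation list (left) and the cholesterol synthesis and lipogenesis list (right), with dotted lines at 1.5-fold. The list medians were -0.73 and 0.69, and Cilp was at -1.03 and Idi1 at 1.08.

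In barcodes of the smooth muscle-like class, class II MHC transcripts were lower and collagen transcripts higher in db/db and salt, as were fibroblast markers as a sum. The class was 1 cluster (cluster 11), in which each endothelial marker was found in 84.2% and each pericyte marker in 63.5% of barcodes on average. Endothelial markers summed to 12863 and 13259 CPM and pericyte markers to 11730 and 11139 CPM, above its smooth muscle markers (7117 and 8551 CPM). Cd74 was at 714 CPM (673 to 757) and 38.2 CPM (29.7 to 48.3), a log2 ratio of -3.91, H2-Aa at 191 and 9.40 CPM (-3.38), H2-Eb1 at 137 and 8.85 CPM (-2.97) and H2-Ab1 at 229 and 22.7 CPM (-2.87). Thinned to 1500 UMIs, 35.1% (26.4 to 44.6%) of db/+ and 2.59% (0.537 to 7.37%) of db/db and salt cells held a Cd74 UMI, and unthinned, at 14054 and 14654 UMIs, 50.9 and 5.83%. All 14 antigen presentation genes were at least 1.5-fold lower (median -1.64, -1.79 to -1.55), as were 18 of 20 interferon genes (median -1.17, -1.30 to -0.98). The interferon median was -0.70 with a pseudocount of 50 CPM. Vcam1 was at 110.2 and 12.7 CPM (-2.40), in a leukocyte adhesion list with a median of -0.38.

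The fibrillar collagen list had a median of 0.51 (0.32 to 0.59) in these cells, above all random lists, with 10 of 23 members at least 1.5-fold higher and none lower, among them the crosslinking enzyme Loxl1 (16.7 and 46.5 CPM, 1.08), Eln (108 and 226 CPM, 1.00), Col5a1 (0.95), Col1a2 (187 and 314 CPM, 0.72) and Col3a1 (107 and 176 CPM, 0.68). Fibroblast markers, which include Col1a1, Col1a2 and Col3a1, summed to 1600.3 and 3296 CPM in the same cells, and cardiomyocyte markers to 116 and 207 CPM. More fibroblast RNA in these barcodes thus cannot be told apart from a rise of collagen in smooth muscle cells. The contractile list was at 0.25, with Actg2 at 0.70 and Acta2 at 2761 and 3460 CPM (0.32), and cholesterol synthesis at 0.23. Complement was at 0.39, with no member 1.5-fold apart, and matrix degradation at 0.21, with Adamts5 at 0.68 and Mmp2 at 0.65; with cells thinned these medians were -0.19 and -0.024. Medians of the other lists lay between -0.16 (mesenchymal transition) and 0.13 (basement membrane).

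Single genes with higher levels in smooth muscle-like cells were Cyp26b1 (4 and 128 UMIs, 2.48 and 70.8 CPM, log2 ratio 2.69), which was at 381 CPM in endothelial-like cells of the same library, Ocel1 (22.3 and 66.4 CPM, 1.24) and Fmo2 (16.1 and 50.9 CPM, 1.22). Endothelial markers in db/db and salt summed to 13259 CPM here and 33354 CPM in endothelial-like cells. For Cyp26b1, endothelial RNA in these barcodes thus cannot be told apart from a change in smooth muscle cells. The water channel Aqp1, highest in endothelial-like cells, was at 75.6 and 197 CPM (1.27), and at a ratio of -0.021 without the 2% of cells with the most UMIs. Dbp was at 126 and 10.5 CPM (-2.73).

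Pericyte-like cells were fewer than 100 in 1 library and their values are given beside those of the main classes. Interferon response (median -1.23, 18 of 20 genes lower), antigen presentation (-1.35, 10 of 11 lower) and leukocyte adhesion (-0.36) were lower, with H2-Q7 at 220.1 and 25.1 CPM (-2.71), and cholesterol synthesis was at 0.36. Fibrillar collagen was at 0.22 and matrix degradation at 0.24, with Mmp2 at 22.0 and 79.2 CPM (1.48), while fibroblast markers summed to 874 and 2986 CPM in these cells. Endothelial markers summed to 20224 and 19566 CPM there, against 31162 and 33354 CPM in endothelial-like cells. Fibroblast activation was at -0.35, with Tagln at 137 and 44.4 CPM (-1.44) and Acta2 at -0.76, both smooth muscle markers, and smooth muscle markers summed to 571 and 417 CPM. Pericyte identity was at 0.17, the renin-angiotensin list at 0.20 and cardiomyocyte transcripts at 0.013, and medians of the other lists lay between -0.14 (fatty acid oxidation) and 0.33 (complement). Erythroid transcripts were at a median of -1.42, with Hbb-bt, an adult beta globin, at 537 and 13.5 CPM (-4.54). Lists of adipocyte, leukocyte and sex check transcripts had fewer than 5 measured members in every class. So had those of complement, mesenchymal transition, the renin-angiotensin system, pericyte identity and cardiomyocyte transcripts in endothelial-like cells, of proliferation, cardiomyocyte and erythroid transcripts in fibroblast-like cells, and of cardiomyocyte and erythroid transcripts in smooth muscle-like cells.

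Across endothelial-like, fibroblast-like and smooth muscle-like cells, 6 genes were at least 1.5-fold higher and 15 at least 1.5-fold lower in all of them. Dbp (log2 ratios -2.22, -2.08 and -2.73 in that order) and Nr1d1 (-1.61, -1.69 and -1.13), parts of the circadian clock, and the interferon-inducible Iigp1 (-2.18, -1.45 and -2.52), Isg15 (-1.42, -1.76 and -1.62) and Bst2 (-1.88, -1.30 and -1.45) were lower in each. Fmo2 (0.79, 0.83 and 1.22) was higher in each. Gm10076 (1.73, 1.76 and 1.96) and Gm10260 (1.57, 2.03 and 1.69) were higher and Gm8797 (-2.15, -2.28 and -2.06) lower, and each has a near-identical copy elsewhere, Rpl41, Rps18 and Ubb, so that their values are uncertain.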

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

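The tests on near-identical gene copies within the interferon lists, on a strain variant, on free RNA as a source of clock transcripts, on the clock phase and on cells with Gm8797 were chosen after the result was seen, and the tests that leave out or compare clusters 4, 13 and 19 after those clusters were seen but before their own values were; the others were written before their values were seen.

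Some gene lists had medians of opposite sign in different classes, each beyond its own counting interval, which is why they are listed here; with 1 library per group the difference between classes was not tested. The complement list had a median log2 ratio of 0.39 in smooth muscle-like and -0.29 in fibroblast-like cells, and the first was -0.19 with cells thinned to 1500 UMIs. The contractile list was at 0.25 in smooth muscle-like and -0.21 in fibroblast-like cells, where smooth muscle markers, some of them list members, summed to 409 CPM in db/+ and 274 CPM in db/db and salt. Fatty acid uptake and handling was at 0.065 in endothelial-like cells, -0.017 there with TMM factors, and -0.20 in fibroblast-like cells, where it was 0.12, 0.20, 0.14 and 0.11, the same sign as in endothelial-like cells, with at least 200 or 1000 genes, at resolution 2 and with 4000 variable genes. Fibrillar collagen and crosslinking was at 0.057 in endothelial-like, 0.51 in smooth muscle-like and -0.13 in fibroblast-like cells, where the first was -0.0055 with TMM factors and the last -0.025 with cells thinned. Over all measured genes the median in endothelial-like cells was 0.057. The endothelial values of fatty acid uptake and of fibrillar collagen lay near it, so their sign does not set these lists apart from other genes there. Fibroblast markers, some of them members of this list, summed to 1600.3 and 3296 CPM in smooth muscle-like cells of db/+ and of db/db and salt, so fibroblast RNA may add to the value there. Matrix degradation was at 0.14 in endothelial-like, 0.21 in smooth muscle-like and -0.11 in fibroblast-like cells, and the second was -0.024 with cells thinned.

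Lower interferon and antigen presentation transcripts in endothelial-like cells of db/db and salt were weighed against technical sources. Leukocyte RNA is argued against, since Ptprc, Tyrobp, Fcer1g, Cd52, Coro1a and Laptm5 together reached 0.874% of the Cd74 level in db/+ endothelial-like cells, and so are depth (antigen median -1.30 with cells thinned), shared reads (-1.23 over 10 members without near-identical copies) and a strain variant in the H2 region alone (-1.13 over 23 members on chromosomes other than 17, of which 21 were at least 1.5-fold lower). Clusters 4, 13 and 19, with 974 db/+ cells, do not account for all of it, since the antigen median over the other cells was -0.72. What stays open is that hearts of the db/+ group may have differed from each other. Dbp was 3.49-fold higher inside than outside those clusters (128 and 36.6 CPM), though Dbp was used for clustering. Its ratio between the db/+ cells with the most and the fewest interferon and antigen UMIs was 5.48 in endothelial-like and 1.33 in fibroblast-like cells, which left it undecided. From the fewest to the most, Gm8797 went from 14 to 212 UMIs and Nr1d1 from 54 to 148 in db/+ endothelial-like cells. In those of db/db and salt they went from 5 to 6 and from 20 to 22. In db/+ fibroblast-like cells they went from 30 to 36 and from 67 to 103. The db/+ cells with a Gm8797 UMI held 2.14-fold more Dbp in endothelial-like and 2.13-fold more in fibroblast-like cells than cells without, and 0.550 and 0.568 times the Arntl, as a mix of animals would need (0.932 and 1.32 for Dbp in db/db and salt). The ratios of db/db and salt are imprecise, with 10 and 30 Dbp UMIs in its cells with Gm8797, and cells were not thinned for this split. Antigen and interferon medians were 0.97 and 0.59 higher in db/+ endothelial-like cells with a Gm8797 UMI and only 0.14 and 0.071 higher in such fibroblast-like cells. Single genes were apart in the latter too, H2-Q7 at 22.6 with and 13.1 CPM without a Gm8797 UMI and Iigp1 at 83.7 and 61.6 CPM. For the antigen and interferon lists the split thus bears mainly on the endothelial part, and for the clock genes on both classes. An effect of genotype or salt stays possible and untested.

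Clock transcripts differed in every main class, with Dbp and Nr1d1 lower in db/db and salt. A shift of the clock phase between the collections is consistent with Arntl, Npas2, Clock and Nfil3, which peak opposite to Dbp, having median log2 ratios of 0.35, 0.64 and 0.67 in endothelial-like, fibroblast-like and smooth muscle-like cells, while output genes had medians of -0.65, -0.47 and -0.76; Hlf (0.25) and Per2 (0.37) went the other way in fibroblast-like cells. Free RNA from 1 class alone is argued against. Judged by how much of its markers arrived, any 1 other class of at least 50 cells could bring at most 42.0% of the db/+ Dbp level of a main class (upper counting bound 54.2%, from pericyte-like into smooth muscle-like cells), where at least 79.6% was missing in db/db and salt. Endothelial-like cells could bring 30.4% (upper bound 36.8%) into smooth muscle-like cells. Several sources together were not tested, so free RNA from a pool of classes stays open there. A first form of this test, the lowest Dbp level of a main class as a share of the highest class (30.8%, lower bound 25.3%), had not decided and was replaced after it was seen. Within the db/+ library, cells with a Gm8797 UMI also held more Dbp and less Arntl than cells without, in endothelial-like and in fibroblast-like cells. Times of collection are not given in the sources used here. A difference in time between the groups, a difference between db/+ hearts and an effect of genotype or salt on the clock thus cannot be told apart.

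Some short transcripts, Gm10076 and Gm10260, were higher in db/db and salt in every main class. A length bias is argued against, since genes with transcripts under 700 bases differed from the others by medians of -0.043, 0.040 and 0.026 in endothelial-like, fibroblast-like and smooth muscle-like cells. Reads shared with near-identical copies may play a part: Gm10260 is 99.1% identical to Rps18, which was lower (-0.66, -0.49 and -0.47), but Gm10076 is 99.5% identical to Rpl41, which was not lower (0.011, 0.12 and 0.12). Summed levels of copy and closest gene differed by up to 0.49 in absolute log2 ratio, between the limits set for a decision, so this could not be settled and no biological source was tested.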

How the results depend on the processing

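The alternatives that left out mixed barcodes, joined pericyte-like and smooth muscle-like cells, left out clusters of over 95% of 1 library, or named endothelial subtypes without regard to their top 10 genes were chosen after the data were seen, the clusters left out being those of the test of a db/+ subset. No paired analysis was possible because each group had 1 library and no test was run. Of 45 values of the 4 class shares 22 stayed within their counting intervals and 23 moved beyond them. As reported, the libraries' intervals overlapped for endothelial-like, fibroblast-like, pericyte-like and smooth muscle-like cells, and 3 of these 4 shares, all but that of fibroblast-like cells, changed sign under some alternative. The intervals came apart for endothelial-like cells at resolution 2 (60.5 and 56.5%) and with at most 5% mitochondrial UMIs (57.6 and 53.0%), and for fibroblast-like cells with the latter (30.4 and 38.1%). Of 1674 list medians 1434 stayed, 214 moved and 26 took the opposite sign to a value whose interval excluded 0, and of 1149 values of named genes these numbers were 979, 169 and 1. Antigen presentation in endothelial-like cells ranged from -1.51 to -0.72, the interferon response there from -1.21 to -0.77, fibroblast activation in fibroblast-like cells from -0.77 to -0.44 and cholesterol synthesis there from 0.26 to 0.83, each with 1 direction throughout. No smooth muscle-like class was found with at most 5% mitochondrial UMIs, so its values have no such alternative. Smooth muscle-like cells (116 and 120) and pericyte-like cells (136 and 85) were few, which widens their counting intervals, and shares of 1 library per group carry no error between hearts. The values that follow are log2 ratios of shares or medians of lists, and the cause was not tested.

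With at most 5% mitochondrial UMIs, shares were at -0.12 (endothelial-like), 0.33 (fibroblast-like) and -0.47 (pericyte-like), and endothelial medians at 0.033 for fatty acid uptake, -1.18 for interferon response and -0.0016 for senescence. With at most 20% the shares were 0.015 (endothelial-like), 0.071 (fibroblast-like), -0.19 (pericyte-like) and -0.11 (smooth muscle-like). With at least 200 genes the endothelial-like share was 0.025, the smooth muscle-like share 0.076 and fibroblast fatty acid uptake 0.12. With at least 1000 genes the endothelial-like share was 0.022, the fibroblast-like share 0.069, fibroblast fatty acid uptake 0.20 and fibroblast pericyte identity 0.0070. With doublets kept, the fibroblast-like, pericyte-like and smooth muscle-like shares were 0.074, -0.17 and 0.0034. At resolution 0.5 the pericyte-like share was 0.12 and the smooth muscle-like share -0.097; at resolution 2 the endothelial-like share was -0.097 and fibroblast fatty acid uptake 0.14. With 4000 variable genes these last were -0.068 and 0.11. With each library clustered alone, the endothelial-like, pericyte-like and smooth muscle-like shares were -0.052, -0.22 and 0.034, and fibroblast pericyte identity 0.026. Without the 2% of cells with the most UMIs, fibroblast pericyte identity was 0.0084, smooth muscle interferon response -1.36 and smooth muscle Aqp1 -0.021.

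With TMM factors, endothelial medians were -0.017 for fatty acid uptake, -0.41 for leukocyte adhesion, -1.51 for antigen presentation, -1.16 for interferon response, -0.0055 for fibrillar collagen, -0.062 for basement membrane, -0.033 for senescence and -0.011 for early response, and fibroblast medians -0.16 for collagen and -0.76 for activation. With the median of gene ratios, endothelial fatty acid uptake was -0.019, vascular tone -0.0014, leukocyte adhesion -0.41, antigen presentation -1.51, interferon response -1.16, fibrillar collagen -0.0071, basement membrane -0.064, senescence -0.035 and early response -0.013, with fibroblast collagen at -0.17 and activation at -0.77. With the mean of each cell's CPM, endothelial fatty acid uptake was 0.069, antigen presentation -1.35, interferon response -0.98 and basement membrane -0.044, fibroblast collagen -0.088 and activation -0.60.

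With a pseudocount of 1 CPM, endothelial antigen presentation was -1.50, interferon response -1.21, fibroblast cholesterol synthesis 0.83 and smooth muscle interferon response -1.45. With 50 CPM, endothelial leukocyte adhesion was -0.23, antigen presentation -1.22, interferon response -0.78, fibroblast cholesterol synthesis 0.26, fibroblast activation -0.44 and smooth muscle interferon response -0.70. With cells thinned to 1500 UMIs, endothelial fatty acid uptake was 0.071, leukocyte adhesion -0.28, antigen presentation -1.30, interferon response -0.93, basement membrane -0.043 and proliferation 0.072. Thinned fibroblast medians were -0.025 for collagen, -0.58 for activation, -0.0036 for mineralocorticoid and salt handling and 0.024 for the renin-angiotensin system, and smooth muscle medians -0.19 for complement and -0.024 for matrix degradation. With no floor on members, endothelial fatty acid uptake was 0.029, fibroblast activation -0.62 and the fibroblast renin-angiotensin system 0.020. Over members of at least 50 CPM, endothelial TGF-beta was -0.066 and smooth muscle matrix degradation -0.0021.

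Without mixed barcodes the pericyte-like share was 0.12, and pericyte-like and smooth muscle-like cells as 1 class had a share of -0.051. Without clusters of over 95% of 1 library, endothelial leukocyte adhesion was -0.26, antigen presentation -0.72, interferon response -0.77, basement membrane -0.035 and senescence -0.029. With subtypes named without regard to the top 10 genes, the capillary share was at -0.032 in place of -0.27 and the arterial share at 0.13 in place of 0.22, and the others stayed.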

Other observations

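The test reported here was written before its result was seen, and the clock genes and mesothelial markers below were looked at after the data were seen.

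Clock genes other than Dbp and Nr1d1 also lay apart between the libraries. Arntl, a core activator of the clock, had log2 ratios of 0.48, 1.08 and 0.87 in endothelial-like, fibroblast-like and smooth muscle-like cells, and Npas2, its partner in some tissues, was at 0.74 in fibroblast-like and 0.75 in smooth muscle-like cells. Tef (-1.01, -0.55 and -0.56), Per3 (-0.48, -0.38 and -0.82) and Nr1d2 (-0.80, -1.18 and -0.70) were lower in each class. Barcodes with UMIs of at least 3 of 8 mesothelial markers were 0 of 4865 in db/+, which allows up to 0.0758% of barcodes that pass this rule, and 2 of 4100 (0.0488%) in db/db and salt, both within the endocardial-like class. That limit covers counting error only and does not bound the share of mesothelial cells, since shallow cells can miss these UMIs.

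Higher Cyp26b1 in endothelial-like cells of db/db and salt raised the hypothesis of a wider response to retinoic acid. Dhrs3, which reduces retinaldehyde, was at 186 and 289 CPM (log2 ratio 0.61). Over 5 other retinoid genes the median was 0.21, with Rarb at 0.38, Rarg at 0.37, Tgm2 at 0.21, Rxra at 0.14 and Rara at -0.0046. This median lay just above the limit written beforehand for a wider response. With the TMM shift of 0.081 subtracted in full, a step that was not part of the written prediction, it was 0.13, between the limits set for a decision. A wider response may thus exist and was not settled.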
